A study of Homo sapiens with 12 samples.

How the data were processed

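Gene expression was measured in 3 human soft tissue sarcoma cell lines, each left untreated or given taurolidine (250 µmol/l), TRAIL (50 ng/ml) or both agents for 6 h, with 1 array for each line and treatment and 12 arrays in all. Per the labels' protocols, total RNA was extracted with acid guanidinium thiocyanate and phenol, and biotinylated cRNA was made with the Affymetrix 3' in vitro transcription procedure from 4 to 5 µg of total RNA. The deposited values are array intensity on a linear scale, and MAS5 is named for them per the submitters' processing notes, whose version, detection calls and scaling target are not given in the sources used here. MAS5 takes the weighted average of perfect-match minus mismatch probe brightness and gives every array a common mean. In these values the mean without the lowest and highest 2% lay between 1000.1 and 1000.2 on each array, so the arrays had been scaled to a common trimmed mean. This scaling fixes the mean brightness of an array, and a change in the total amount of messenger RNA per cell is therefore not visible in the values as deposited.

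The table held 54675 probe sets. The platform annotation gave 41097 of them a single gene, 1801 several genes and 11777 no listed gene. The Entrez number of 41043 of the single-gene probe sets was found in the gene reference and gave the current symbol. Probe sets with several genes were used to name none, and 62 control probe sets were left out of the tests. A probe set was tested if it exceeded the median of the whole table, 136.5, on at least 3 arrays, which 32421 did. Where several tested probe sets belonged to a gene, as for 7169 genes, the one with the highest mean stood for it, which left 14221 genes. Values entered as log2(value + 11.8), where 11.8 is the 10th percentile of the table, so fold changes of dim genes are understated. No further normalisation was applied.

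Linear models were fitted with limma 3.58.1 in R 4.3.3, with treatment and cell line as terms and moderated errors (6 residual and 1.99 prior degrees of freedom). All 12 arrays shared 1 estimate of the spread, because no line has a repeated treatment. Differences between lines in the response to an agent thus enter the error of every contrast. The contrasts were taurolidine, TRAIL and their combination against untreated cells, TRAIL added to taurolidine, taurolidine added to TRAIL, the departure of the combination from additivity on the log2 scale, and an F test over all treatments. The p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The models, the filter, the constant, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined, unless stated otherwise. A first pass over the alternative analyses came before the final computation, and it changed none of these choices.

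Arrays of 1 cell line were paired across treatments because they came from the same line. Their deviations from the treatment means correlated at 0.852 to 0.904 across genes within a line and at -0.534 to -0.386 between lines. The 3 deviations of a treatment sum to 0, so negative values between lines follow by construction. Those within a line show only that the lines differed. No 2 arrays shared more than 0.002% of their values. Nothing in the labels says whether the arrays of a line were separate cultures, so the p-values measure only the spread between these arrays, part of which may be technical. There was no replicate within a line, and the number of arrays limits the precision.

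Genes were named by a fixed rule. For each treatment against untreated cells it took the 10 largest rises and the 10 largest falls among genes that passed the threshold in the same direction in all 3 lines. It took 5 in each direction for the other contrasts, and, where fewer than 5 passed, the genes of smallest p with a shared direction, given as not passing. It also took the 3 largest rises and falls within each line, up to 4 members of each gene list with the largest change, passing ones first, and 9 genes of TRAIL signalling and its inhibitors. The 30 gene lists held 593 genes, of which 496 were tested; the others are not analysed here. Lists were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over the 30 lists. Zinc finger, histone, metallothionein, heat shock and ribosomal protein genes belong to families of similar sequence, and their probe sets may detect relatives.

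The procedure was tested on simulated data for 14221 genes with 200 genes changed, over 10 runs. For the taurolidine contrast it recovered 4.48% of changes of 0.5 on the log2 scale, 51.0% of changes of 1 and 85.2% of changes of 2, with 5.94% of calls false. For the TRAIL contrast these shares were 4.03%, 55.8% and 88.2%, with 6.11% of calls false. For the departure from additivity they were 0%, 18.7% and 69.7%, with 7.29% of calls false.

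The alternatives fixed beforehand were no constant, a constant at the 25th percentile, quantile normalisation, equal array medians, no filter, no cell line term, only the arrays of the groups compared, the mean over probe sets, and leaving out each line. Scaling to the poly-A spike-in controls within each line, leaving out 1 array with bright hybridisation controls, main effects over both levels of the other agent, the test of line by agent differences, and the restriction of counts within a line to genes over 136.5 on both arrays were chosen after seeing the data. Control probe sets were compared by exact two-sided permutation of the arrays with and without taurolidine within lines, which has 216 arrangements and a smallest possible p of 0.0093.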

Results

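The series set out to compare untreated soft tissue sarcoma cells with cells given taurolidine, TRAIL or both, under a title that asks about synergy of the 2 agents. Taurolidine is a taurine derivative used against microbes that also kills tumour cells in culture. TRAIL is the ligand, encoded by TNFSF10, of the death receptors encoded by TNFRSF10A and TNFRSF10B. The lines were A-204, labelled rhabdomyosarcoma, SK-LMS-1, labelled leiomyosarcoma, and VA-ES-BJ, labelled epithelioid sarcoma. Each line gave 1 array for each of the 4 treatments, so every mean below rests on n = 3 lines, and errors are standard errors from the model unless an SD is named. The median signal of an array lay between 123.2 and 155.4 in the MAS5 unit.

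The untreated lines differed in marker genes, which followed their labelled origin only in part. SMARCB1, a chromatin remodelling subunit whose loss is typical of epithelioid sarcoma, had a signal of 152 in VA-ES-BJ, against 1240 in A-204 and 3530 in SK-LMS-1. KRT19, an epithelial keratin, stood at 16200 in VA-ES-BJ, 9.33 in A-204 and 27.9 in SK-LMS-1. The smooth muscle genes TAGLN and CNN1 were brightest in SK-LMS-1, with signals of 8950 and 661. In A-204 they were 623 and 17.7, and in VA-ES-BJ 3910 and 162. ACTA2, of the same list, was brightest in VA-ES-BJ, at 4980 against 1690 in SK-LMS-1, and MYH11 stood at 137 in SK-LMS-1. The median of 8 smooth muscle genes was 5320 in SK-LMS-1, 1150 in A-204 and 2070 in VA-ES-BJ. The 4 skeletal muscle genes tested, of 13 listed, did not set A-204 apart, with medians of 241 in A-204, 272 in SK-LMS-1 and 244 in VA-ES-BJ. The other listed genes, MYOD1 and MYOG among them, were not tested. DES, the muscle intermediate filament gene, was near the table median in each line, at 132 in A-204, 127 in SK-LMS-1 and 145 in VA-ES-BJ. Epithelial genes other than keratins were brightest in A-204 in several cases, as EPCAM had a signal of 1910 in A-204, 13.8 in SK-LMS-1 and 130 in VA-ES-BJ, and DSP, a desmosome gene, 3860, 36.2 and 46.7. The median of the 10 epithelial genes was 572 in A-204, 57.3 in SK-LMS-1 and 211 in VA-ES-BJ. Over all 10 SWI/SNF subunits the median untreated signal was 3670 in A-204, 3620 in SK-LMS-1 and 3870 in VA-ES-BJ. Markers of other cells had list medians of 139 to 181 for leukocytes, 138 to 152 for erythroid cells and 175 to 244 for endothelium, with 6, 3 and 5 of their genes measured. Single markers stood higher, with CORO1A at 1400 in A-204 and 987 in VA-ES-BJ, EGFL7 at 1530 and 895 in the same lines, and TIE1 at 2470 in SK-LMS-1. These are values of 1 untreated array per line, without a test. Between 1687 and 1753 genes differed by at least 4-fold between 2 untreated lines.

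Control probe sets were compared between arrays with and without taurolidine. The 27 probe sets for poly-A spike-in RNAs, which are added to the sample before labelling, were higher with taurolidine by 0.59 on the log2 scale (SD 0.11, 1.51-fold), in 3 of 3 lines (exact permutation p = 0.0093, adjusted p = 0.033 over 7 measures). The 18 hybridisation control probe sets differed by -0.02 (SD 0.22, exact permutation p = 0.95). The ratio of 3' to 5' signal, a measure of RNA integrity and labelling, differed by 0 for GAPDH (SD 0.02, exact permutation p = 0.95) and for ACTB (SD 0.03, exact permutation p = 0.89). For a further control transcript of the array design the same ratio was 0.82 higher with taurolidine (SD 0.14, exact permutation p = 0.0093, adjusted p = 0.033). The 3' to 5' ratio of the spikes differed by 0.09 (SD 0.04, exact permutation p = 0.12), and the 18S and 28S ribosomal RNA probe sets by 0.47 (SD 0.36, exact permutation p = 0.21).

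**Figure D1:**
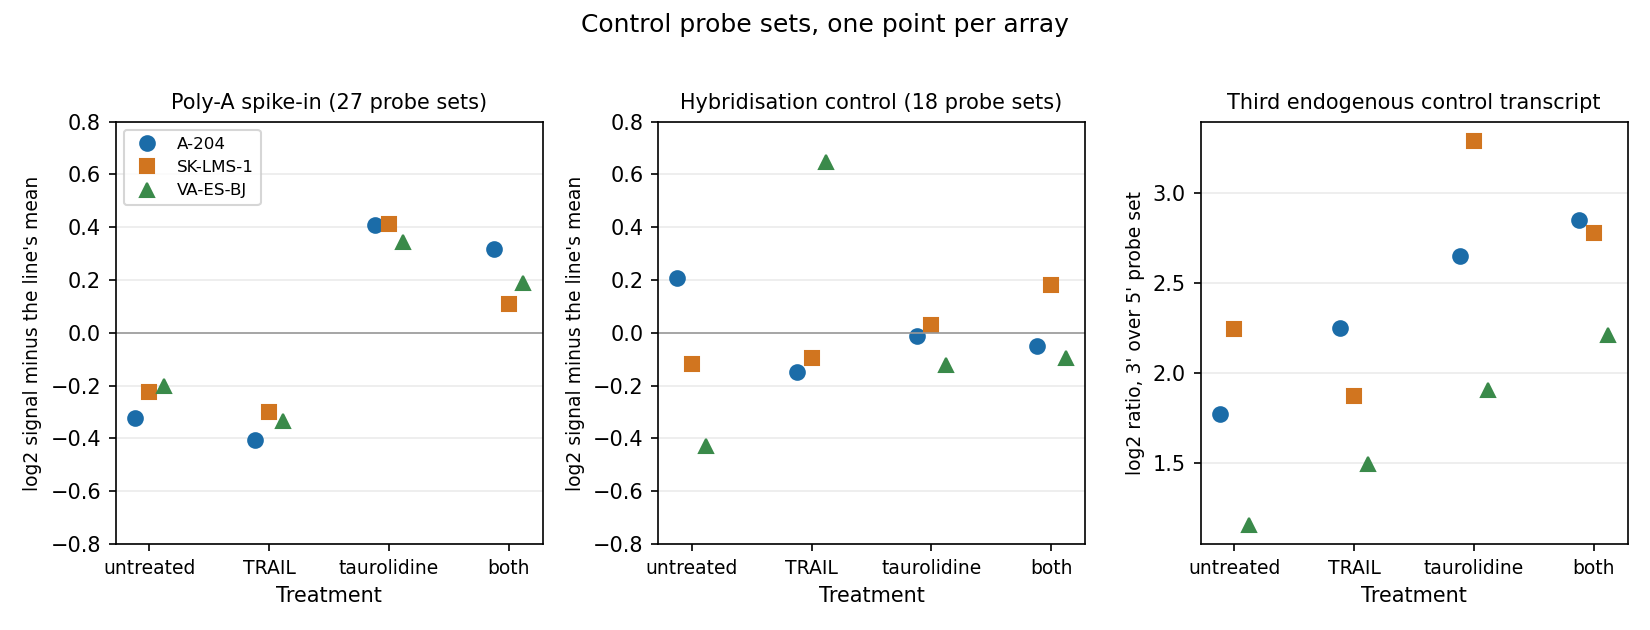
Control probe sets on each of the 12 arrays by treatment and cell line, one point per array: mean log2 signal of poly-A spike-ins and of hybridisation controls as the deviation from the line's mean, and the log2 ratio of 3' to 5' signal of a further control transcript. The poly-A spike-ins were higher with taurolidine by 0.59 on average, and the hybridisation controls of the VA-ES-BJ array with TRAIL stood 1.82-fold above the other arrays of that line.

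With taurolidine alone, FOS and FOSB, which encode AP-1 transcription factor subunits, rose by 5.24 ± 0.76 and 4.85 ± 0.71 on the log2 scale, or 37.7-fold and 28.8-fold (adjusted p = 0.0048 and 0.0053). ATF3, a stress-induced transcription factor, rose 10.2-fold (3.34 ± 0.45, adjusted p = 0.0035), EGR3 8.11-fold (3.02 ± 0.13, adjusted p = 0.00011), and the nuclear receptor gene NR4A2 7.15-fold (2.84 ± 0.21, adjusted p = 0.00046). HES1, a Notch target, rose 7.05-fold and PTGS2, the inducible cyclooxygenase, 6.20-fold. The largest rise was that of RNA45SN5, the 45S precursor of ribosomal RNA, at 50.0-fold (5.64 ± 0.40, adjusted p = 0.00046), and its other probe set rose by 4.85. ARC and the antisense transcript ZNF143-AS1 rose 6.57-fold and 9.41-fold from signals of 19.3 and 20.8, which lie under the table median, so their folds depend on the added constant.

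The largest fall after taurolidine was that of MED26, a subunit of the Mediator complex, which was 15.6-fold lower (-3.97 ± 0.34, adjusted p = 0.00068), with a mean signal of 141 against 2130. KCTD21 was 10.9-fold lower, the splicing factor gene CCDC12 9.88-fold, TIGD5 9.37-fold, WDCP 9.09-fold, and DUSP16, a phosphatase of stress-activated kinases, 8.70-fold. The other 2 probe sets of DUSP16 gave smaller falls, at -1.66 and -0.60. The zinc finger genes ZNF680, ZNF708, ZNF584 and ZNF267 were 8.01-fold, 7.31-fold, 7.10-fold and 6.95-fold lower (adjusted p from 0.00072 to 0.026), with the caution that members of this family are similar in sequence. KCTD21, TIGD5 and ZNF708 stood at mean signals of 52.4, 66.6 and 54.8 with taurolidine and never over the table median, so their folds and rank depend on the added constant.

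Altogether 2729 of 14221 genes passed the threshold for taurolidine, 1099 higher (40.3%) and 1630 lower, all in the same direction in the 3 lines, and 728 of them by at least 2-fold. At an unadjusted p under 0.05 there were 4910 genes, against 711 expected with no change. The higher share was 52.0% with quantile normalisation and 74.2% with equal array medians, which moved the median of all genes by 0.22. Scaling to the poly-A spikes, chosen after seeing the data, moved that median to -0.64 and gave 34 genes higher and 8317 lower, with 888 of the 2729 genes turned in direction. Without A-204 380 genes passed, without SK-LMS-1 415 and without VA-ES-BJ 354, without the cell line term 143, and with only the 6 arrays compared 0 (limma, 3776 at an unadjusted p under 0.05).

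**Figure D2:**
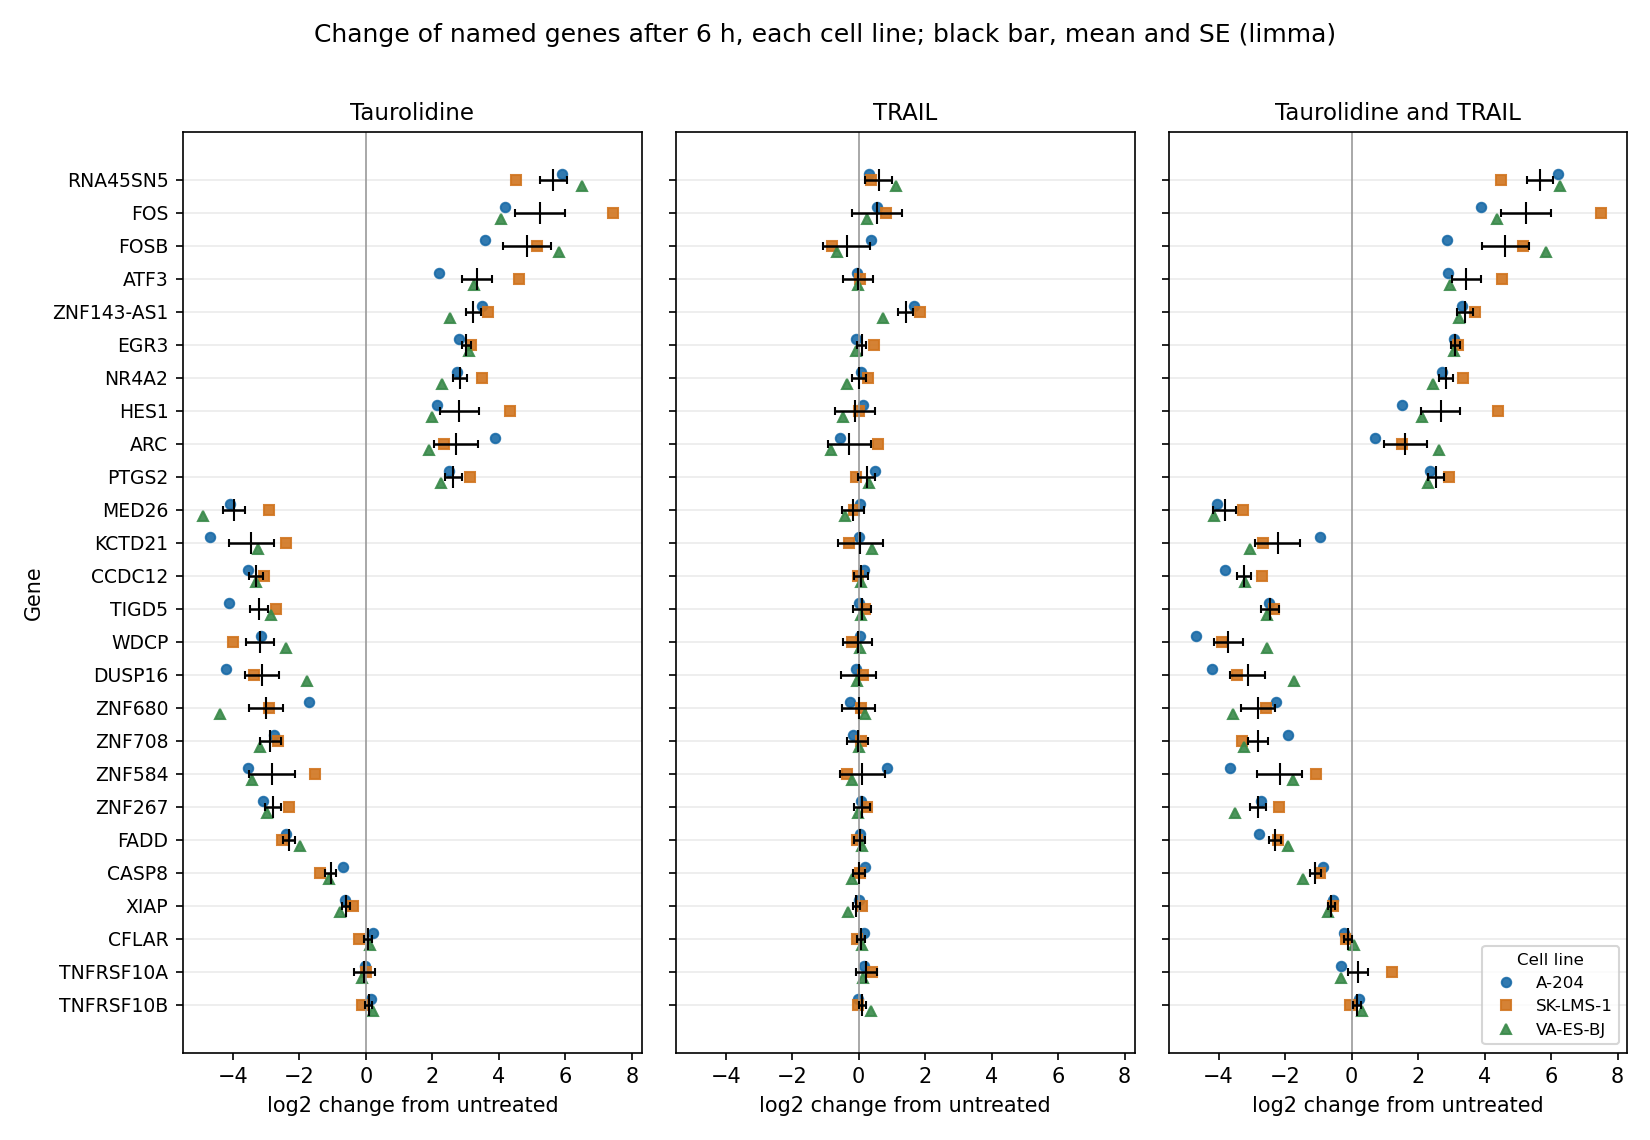
Log2 change from untreated cells of the 20 genes named for taurolidine and of 6 genes of death receptor signalling, with 1 coloured point per cell line and a black bar for the mean over 3 lines and the standard error from the model on all 12 arrays, for taurolidine, TRAIL and both agents. FOS rose by 5.24 with taurolidine and 5.25 with both agents, and MED26 changed by -3.97 and -3.82, while none of these genes passed the threshold with TRAIL alone.

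Among the genes of TRAIL receptors and extrinsic apoptosis, 5 of 21 measured fell with taurolidine and none rose. FADD, the adaptor that joins death receptors to caspase 8, was 4.94-fold lower (-2.30 ± 0.18, adjusted p = 0.00054), at -2.41 in A-204, -2.51 in SK-LMS-1 and -1.99 in VA-ES-BJ. CASP8, the initiator caspase of this pathway, was 2.08-fold lower (-1.06 ± 0.17, adjusted p = 0.0070). APAF1, the scaffold of the apoptosome, fell by 1.03 ± 0.14, and the inhibitor of apoptosis gene XIAP fell by 0.59 ± 0.11. Adjusted over the list alone the count was also 5. The receptor genes TNFRSF10A (-0.05 ± 0.31), TNFRSF10B (0.08 ± 0.11), TNFRSF10C (0.84 ± 0.72) and TNFRSF10D (-0.01 ± 0.23) did not pass, nor did TNFSF10 (0.03 ± 0.34), CFLAR (0.05 ± 0.12), the caspase 8 inhibitor gene, or MCL1 (-0.52 ± 0.22, adjusted p = 0.14). The mean of TNFRSF10D averages opposite changes, at 0.21 in A-204, 0.34 in SK-LMS-1 and -0.59 in VA-ES-BJ. In the test of line differences given below, chosen after seeing the data, TNFRSF10D was called (limma, adjusted p = 0.049). Over arrays with and without TRAIL its changes there were 0.36, 0.34 and -0.55 in the same order. As a whole the list was not called (camera adjusted p = 0.76, adjusted p = 0.84 with an estimated correlation, fry adjusted p = 0.058), with a median change of 0.03 and a mean of -0.13. Other probe sets gave the opposite sign for 1 of 2 of TNFSF10, 3 of 3 of TNFRSF10B, 8 of 11 of CFLAR and 1 of 6 of XIAP. The 4 other probe sets of MCL1 were all lower, from -1.18 to -0.22.

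Camera at the preset correlation called 10 of the 30 lists with taurolidine, all higher, and none with an estimated correlation, where the smallest adjusted p was 0.47. Fry called 14, but not 3 of those 10, ribosomal proteins (fry adjusted p = 0.099), DNA replication and S phase (0.063) and metallothioneins (0.063). Spike scaling and equal array medians move all genes of an array alike, so they shift every list by the same amount and leave its distance from all genes unchanged. In oxidative phosphorylation, 16 of 25 measured genes rose and none fell, and 21 rose adjusted over the list alone (camera adjusted p = 2.7e-09, adjusted p = 0.47 with an estimated correlation). NDUFA1, a complex I subunit, rose by 0.69 ± 0.11 and COX5B, of cytochrome c oxidase, by 0.52 ± 0.09. The list median was 0.43 above that of all genes, and 0.16 above it with quantile normalisation; its own value of 0.43 became -0.21 under spike scaling. Of 25 proteasome subunits 5 rose, among them PSMB3 (0.56 ± 0.12), and 13 adjusted over the list alone (adjusted p = 1.4e-05, adjusted p = 0.47 with an estimated correlation). Of 12 replication-dependent histones 4 rose, with H3C2 at 1.40 ± 0.23 and H2AC8 at 1.12 ± 0.12, and 5 adjusted over the list alone (adjusted p = 0.00059, adjusted p = 0.47 with an estimated correlation). None of 21 ribosomal protein genes passed, in limma over all genes or adjusted over the list alone, although the list was called at a median of 0.30 (adjusted p = 6.0e-04, adjusted p = 0.53 with an estimated correlation). The medians of the proteasome, histone and ribosomal lists were -0.32, -0.12 and -0.34 under spike scaling, and those of the proteasome and ribosomal lists were 0.03 and -0.02 relative to all genes with quantile normalisation. On the same arrays the poly-A spikes were 0.59 higher.

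Of 26 immediate-early and AP-1 genes, 8 rose and 1 fell, or 9 and 2 adjusted over the list alone (adjusted p = 0.0037, adjusted p = 0.47 with an estimated correlation). Its largest changes were those of FOS, FOSB, EGR3 and NR4A2, and its median of 0.70 was 0.07 under spike scaling. Of 22 genes of the NRF2 and glutathione response 5 rose and 1 fell, the same counts as adjusted over the list alone (adjusted p = 0.032, adjusted p = 0.47 with an estimated correlation). TALDO1, of the pentose phosphate pathway, rose by 0.54 ± 0.11 and AKR1C1, an aldo-keto reductase gene, by 0.58 ± 0.17, while GCLC, the catalytic subunit of glutathione synthesis, fell by 0.59 ± 0.14. In hypoxia and glycolysis 4 of 20 rose, with ADM at 1.67 ± 0.46, and also 4 adjusted over the list alone (list camera adjusted p = 0.0083, adjusted p = 0.47 with an estimated correlation). In DNA replication and S phase 5 of 24 rose, with MCM5 at 0.62 ± 0.12, and 6 adjusted over the list alone (list camera adjusted p = 0.026, adjusted p = 0.51 with an estimated correlation). Of 15 aminoacyl-tRNA synthetases 2 rose, VARS1 (0.58 ± 0.12) and CARS1 (0.36 ± 0.09), and 2 adjusted over the list alone (adjusted p = 0.00071, adjusted p = 0.47 with an estimated correlation). None of 9 metallothionein and zinc response genes passed over all genes or adjusted over the list alone, with MT1M at 1.43 ± 0.62. The list itself was called (camera adjusted p = 0.032, adjusted p = 0.51 with an estimated correlation). Under spike scaling the medians of these 5 lists, in the order given from the NRF2 list on, were -0.37, -0.35, -0.42, -0.39 and -0.28, and with quantile normalisation they were 0.13, 0.17, -0.03, 0.02 and 0.03 relative to all genes, against 0.27, 0.29, 0.22, 0.25 and 0.36 as deposited.

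The other lists were not called by camera with taurolidine. Fry called 7 of them: the BCL2 family (adjusted p = 0.0062), TGF-beta and SMAD targets (0.0065), autophagy and lysosome (0.0078), the integrated stress response and smooth muscle (0.017 each), and heat shock and epithelial genes (0.029 each). Fry sets a list against no other genes, so these calls depend on the scaling. In the order given, their medians were 0.19, -0.11, 0.11, 0.05, 0.20, 0.22 and 0.57 as deposited. Under spike scaling they were -0.44, -0.75, -0.53, -0.59, -0.43, -0.42 and -0.07. In the integrated stress response 6 of 24 rose and 2 fell (7 and 4 adjusted over the list alone). PPP1R15A, a phosphatase subunit that reverses translation arrest, rose 4.24-fold and ATF4 2.05-fold, while SESN2, a stress-induced regulator of mTORC1, was 2.82-fold lower. Of 21 p53 targets 3 rose and 5 fell (3 and 5 adjusted over the list alone): GADD45A rose 3.02-fold, and PPM1D, a phosphatase that dampens p53, was 4.04-fold lower. PMAIP1, which encodes the BH3-only protein NOXA, rose 2.28-fold (1.19 ± 0.09, adjusted p = 0.00046) and was 1 of 2 genes to rise among 17 of the BCL2 family (2 adjusted over the list alone). None of 19 TGF-beta and SMAD targets rose and 4 fell (4 adjusted over the list alone), led by SMAD7, a feedback inhibitor, at -2.48 ± 0.41. In autophagy and lysosome 7 of 22 rose and 2 fell, with GABARAPL1 at 0.75 ± 0.15 and ATG16L1 at -0.88 ± 0.25, the same counts as adjusted over the list alone. In mitosis and G2/M 4 of 27 fell, among them MKI67 at -0.66 ± 0.09, and 1 rose (4 and 1 adjusted over the list alone). Of 21 NF-kB targets 2 rose and 2 fell (3 and 2 adjusted over the list alone), with the cytokine gene IL6 at 1.40 ± 0.32 and the feedback inhibitor gene TNFAIP3 at -1.05 ± 0.19. The median of this list was 0.33 in A-204, 0.35 in SK-LMS-1 and -0.09 in VA-ES-BJ. Its members NFKBIA, IRF1 and CXCL2 differed between lines in the test given below, chosen after seeing the data. NFKBIA changed there by 0.03, 1.57 and -1.62 in the same order.

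In heat shock and cytosolic chaperones 3 of 20 rose (2 adjusted over the list alone), led by IER5 at 1.29 ± 0.27, and HSPA6 did not pass at 3.50 ± 1.26. Among 18 endoplasmic reticulum chaperones 2 rose (1 adjusted over the list alone), with DNAJB9 at 0.89 ± 0.12. In cholesterol synthesis 1 of 14 rose and 1 fell (5 and 2 adjusted over the list alone), the latter SQLE at -1.01 ± 0.18. Of 17 interferon-stimulated genes 2 rose and 1 fell, with the same counts adjusted over the list alone. TIMP1, at 0.61 ± 0.12, was the only gene to pass among 23 of the extracellular matrix (1 adjusted over the list alone). In the line identity lists none of 8 smooth muscle genes passed, TNNT1 rose among 4 skeletal muscle genes, KRT18 and MUC1 rose among 10 epithelial genes, and ARID1A fell among 10 SWI/SNF subunits, with the same counts adjusted over the list alone. None of the leukocyte, erythroid and endothelial markers passed in limma, over all genes or adjusted over the list alone. The adjusted p of these 20 lists was 0.07 or more with camera, and at most 0.90 with an estimated correlation. Median, mean and test differed in sign for the skeletal muscle list (-0.09, -0.03 and up), the endothelial list (-0.14, 0.24 and up) and the list of TRAIL receptors and extrinsic apoptosis (0.03, -0.13 and down).

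TRAIL alone left every gene under the threshold. The genes with the smallest p among those that shared a direction in the 3 lines were FKBP6 (1.38 ± 0.22), ZNF143-AS1 (1.41 ± 0.24), LOC100130987 (0.64 ± 0.15), ARHGAP27P1 (0.60 ± 0.14) and AGO2, an Argonaute gene (0.62 ± 0.15), above untreated cells. Below them stood TTF2 (-0.71 ± 0.12), FATE1 (-0.85 ± 0.14), VIPR2 (-1.48 ± 0.26), RPH3A (-1.07 ± 0.19) and SLAMF9 (-1.88 ± 0.35). Their adjusted p was 1 in each case, and FKBP6, ZNF143-AS1 and VIPR2 without TRAIL and RPH3A and SLAMF9 with it were never over the table median. TNFRSF10A (0.23 ± 0.31), TNFRSF10B (0.11 ± 0.11), TNFRSF10C (-0.13 ± 0.72), TNFRSF10D (-0.02 ± 0.23), TNFSF10 (0.14 ± 0.34), CASP8 (0.01 ± 0.17), CFLAR (0.07 ± 0.12), XIAP (-0.07 ± 0.11) and MCL1 (0.18 ± 0.22) also had an adjusted p of 1. Limma called 0 of 14221 genes, with 566 at an unadjusted p under 0.05 against 711 expected with no change. The main effect over both taurolidine levels, chosen after seeing the data, also called 0, with 400 at an unadjusted p under 0.05. The error in these tests also holds differences between lines in the change with taurolidine. Such differences had an unadjusted p under 0.05 for 2744 genes (limma, chosen after seeing the data). The errors can thus be too large for TRAIL, and counts under 711 do not show that TRAIL changed nothing.

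Camera at the preset correlation called 6 lists with TRAIL, all higher, and neither camera with an estimated correlation (smallest adjusted p = 0.67) nor fry called any. The medians were 0.25 for ribosomal proteins (adjusted p = 7.7e-10), 0.12 for oxidative phosphorylation (adjusted p = 6.3e-06), 0.11 for proteasome subunits (adjusted p = 5.3e-06), 0.14 for metallothioneins, 0.08 for aminoacyl-tRNA synthetases and 0.05 for heat shock genes. The ribosomal median was 0.01 in A-204, 0.05 in SK-LMS-1 and 0.67 in VA-ES-BJ, whose array with TRAIL also had hybridisation controls 1.82-fold brighter than the other arrays of the line. The other 5 lists had medians of -0.07 to -0.02 in SK-LMS-1, 0.04 to 0.13 in A-204 and 0.13 to 0.38 in VA-ES-BJ, so their direction was not shared by the lines. No list member passed over all genes, and 1 did adjusted over a list alone, in cholesterol synthesis, where it was lower.

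With both agents, 15 of the 20 genes named for taurolidine were named again. RNA45SN5 rose 50.9-fold (5.67 ± 0.40, adjusted p = 0.00049), FOS 38.0-fold (5.25 ± 0.76), FOSB 24.7-fold (4.63 ± 0.71), ATF3 by 3.45 ± 0.45, ZNF143-AS1 10.7-fold and EGR3 8.72-fold (3.12 ± 0.13, adjusted p = 0.00012). NR4A2, HES1 and PTGS2 rose 7.14-fold, 6.44-fold and 5.79-fold, and the imprinted transcript HYMAI 7.33-fold (2.87 ± 0.79, adjusted p = 0.041). MED26 was 14.1-fold lower (-3.82 ± 0.34, adjusted p = 0.00084), WDCP 13.0-fold, CCDC12 9.43-fold and DUSP16 8.73-fold. PARS2, the mitochondrial prolyl-tRNA synthetase gene, was 8.61-fold lower, SMAD7 7.83-fold, IFT70B 7.18-fold, and ZNF627, ZNF708 and ZNF267 fell by 2.98, 2.81 and 2.81. PARS2, IFT70B and ZNF708 with both agents (64.7, 52.1 and 64.5) and ZNF143-AS1 without (20.8) were never over the table median, so their folds depend on the added constant.

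In total 2679 genes passed for the combination, 1078 higher (40.2%) and 1601 lower, all in the same direction in the 3 lines, with 722 by at least 2-fold and 4946 at an unadjusted p under 0.05. The higher share was 52.6% with quantile normalisation and 73.5% with equal array medians. Scaling to the poly-A spikes gave 56 higher and 5006 lower, with a median of all genes of -0.44. Without A-204 232 genes passed, without SK-LMS-1 499 and without VA-ES-BJ 378, without the cell line term 158, and with only the 6 arrays compared 0 (limma, 3361 at an unadjusted p under 0.05).

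Death receptor genes had similar values with both agents. FADD was 4.93-fold lower (-2.30 ± 0.18), APAF1 2.27-fold lower, CASP8 2.13-fold lower (-1.09 ± 0.17) and XIAP 1.53-fold lower. With 5 of 21 genes lower and 1 higher, the same counts as adjusted over the list alone, the list was not called by camera (adjusted p = 0.61, adjusted p = 0.72 with an estimated correlation) and was called by fry (adjusted p = 0.030), at a median of 0.10 and a mean of -0.16. TNFSF10, TNFRSF10A, TNFRSF10B, TNFRSF10C, TNFRSF10D, CFLAR and MCL1 did not pass, at 0.21, 0.19, 0.16, 0.10, 0.09, -0.12 and -0.50. Camera called 14 lists, 13 higher and 1 lower, with none called at an estimated correlation (smallest adjusted p = 0.49) and 15 by fry. In oxidative phosphorylation 15 of 25 genes rose (22 adjusted over the list alone, adjusted p = 4.2e-09, adjusted p = 0.49 with an estimated correlation), at a median of 0.41 that became -0.04 under spike scaling. Of the histones 4 of 12 rose (6 adjusted over the list alone, adjusted p = 0.0019, adjusted p = 0.49 with an estimated correlation), with H3C2 at 1.66 ± 0.23 and a median of 0.52, or 0.06 under spike scaling. Mitosis and G2/M was the list called lower (adjusted p = 0.042, adjusted p = 0.72 with an estimated correlation), where AURKA, TTK and MKI67 fell by 0.80, 0.73 and 0.54, UBE2C rose by 0.49, and the counts adjusted over the list alone were again 3 and 1. Not all its genes shared a direction in the lines, as CCNB2 went from 9050 untreated to 13300 in A-204 and from 5980 to 4090 in VA-ES-BJ. With taurolidine alone the list median was 0.16 in A-204, -0.24 in SK-LMS-1 and -0.60 in VA-ES-BJ. Of 8 smooth muscle genes CNN1 rose, at 1.39 ± 0.34, and 3 passed adjusted over the list alone (list camera adjusted p = 0.038, adjusted p = 0.49 with an estimated correlation). The list's median of 0.27 was -0.19 under spike scaling. The immediate-early list had 7 genes higher and 2 lower (9 and 3 adjusted over the list alone, adjusted p = 0.013, adjusted p = 0.49 with an estimated correlation), and the proteasome list 6 higher (13 adjusted over the list alone, adjusted p = 3.1e-05, adjusted p = 0.54 with an estimated correlation). With quantile normalisation the medians relative to all genes went from 0.39 to 0.13 for oxidative phosphorylation, 0.30 to 0.01 for proteasome subunits, 0.50 to 0.57 for histones, 0.57 to 0.61 for immediate-early genes, 0.25 to 0.15 for smooth muscle and -0.25 to -0.41 for mitosis and G2/M.

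Adding TRAIL to taurolidine left every gene under the threshold as well. The smallest p with a shared direction belonged to SLFNL1 (1.69 ± 0.24), NSMCE3 (0.88 ± 0.13), FAM78A (1.25 ± 0.20), PRTG (1.24 ± 0.22) and GPR135 (1.61 ± 0.30). On the lower side they belonged to GSX2 (-1.01 ± 0.14), NPTN-IT1 (-1.09 ± 0.18), NRG2 (-0.66 ± 0.12), PREX1 (-1.03 ± 0.20) and ATP6V0E2-AS1 (-0.89 ± 0.18). SLFNL1, FAM78A, PRTG and GPR135 stood at 82.9, 39.8, 61.5 and 17.3 with taurolidine alone, and NPTN-IT1 and ATP6V0E2-AS1 at 51.0 and 78.3 with both agents, never over the table median. CASP8 (-0.03 ± 0.17), CFLAR (-0.17 ± 0.12), TNFRSF10B (0.08 ± 0.11) and XIAP (-0.02 ± 0.11) did not pass. Limma called 0 genes, with 376 at an unadjusted p under 0.05 and a smallest adjusted p of 0.804. The error again holds line differences in the change with taurolidine, so this test can be too strict. No list was called by camera at either correlation or by fry. Without the filter on dim probe sets 1 gene passed.

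Adding taurolidine to TRAIL changed 2298 genes, 928 higher (40.4%) and 1370 lower, 691 of them by at least 2-fold. RNA45SN5 rose 33.5-fold, FOSB 31.8-fold and FOS 26.0-fold, followed by HSPA6, an inducible heat shock protein gene of a family of similar sequence, at 24.0-fold (4.59 ± 1.26, adjusted p = 0.045; 2.44 in A-204, 8.38 in SK-LMS-1 and 2.94 in VA-ES-BJ), and RASD1, a small GTPase gene, at 12.6-fold (3.66 ± 0.83, adjusted p = 0.025), from a signal of 43.0 that was never over the table median, so that its fold depends on the added constant. WDCP, MED26, CCDC12, DUSP16 and ZNF627 were 12.7-fold, 12.5-fold, 9.88-fold, 8.72-fold and 7.96-fold lower. The higher share was 52.6% with quantile normalisation, 71.3% with equal array medians and 0.864% with spike scaling, where 6482 genes passed. Camera called 5 lists (oxidative phosphorylation, histones, proteasome and aminoacyl-tRNA synthetases higher, mitosis and G2/M lower), none with an estimated correlation (smallest adjusted p = 0.69), and fry 11. In the mitosis list not all genes shared a direction. CCNB2 went from 9460 with TRAIL to 13300 with both agents in A-204, and from 5740 to 4090 in VA-ES-BJ. Without the VA-ES-BJ array with TRAIL 1411 genes passed, without each line in turn 256 to 479, without the cell line term 146, and with only the 6 arrays compared 0 (limma, 3323 at an unadjusted p under 0.05).

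No gene passed the threshold for a departure from additivity of the 2 agents. The smallest p with a shared direction belonged to TTF2 (1.01 ± 0.17), SLCO2B1 (2.67 ± 0.44), BICDL1 (1.61 ± 0.27), GALNT7-DT (1.15 ± 0.21) and the pseudogene RPL7AP9 (0.84 ± 0.15) above additivity. Below it stood NPTN-IT1 (-1.32 ± 0.25), CAMK1D (-1.36 ± 0.28), FKBP6 (-1.40 ± 0.31), ARRDC3-AS1 (-1.43 ± 0.34) and PREX1 (-1.10 ± 0.28), and all had an adjusted p of 1. For CASP8 the departure was -0.04 ± 0.24, for CFLAR -0.24 ± 0.17, for TNFRSF10B -0.03 ± 0.16, for XIAP 0.06 ± 0.15 and for MCL1 -0.16 ± 0.31. Limma called 0 genes with 540 at an unadjusted p under 0.05, and the median standard error was 0.2494. That error, too, holds line differences in the change with taurolidine. In the simulation 18.7% of departures of 1 on the log2 scale and 69.7% of those of 2 were recovered, so most departures of 2-fold would be missed with this number of arrays. Camera called 3 lists lower (proteasome subunits, ribosomal proteins and oxidative phosphorylation), none with an estimated correlation (smallest adjusted p = 0.66) or by fry, and their medians were -0.35, -0.67 and -0.37 in VA-ES-BJ against -0.07 to 0.12 in the other lines. The F test over all treatments passed 2551 genes.

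The responses to taurolidine with and without TRAIL overlapped. Of the passing genes 859 rose and 1362 fell in both comparisons with untreated cells and 1 was opposite, against 83.3 and 183.5 for independent lists. The log2 changes of the 2 comparisons correlated across genes at 0.87, where unchanged groups simulated against the same controls gave 0.50, with a covariance of 0.266 against 0.039. The covariance differed from the simulated one by 0.228. The 3 untreated arrays could not be divided, and part of the excess over independent lists may come from these shared controls. The contrasts of taurolidine alone and of taurolidine added to TRAIL compare no array in common. There 530 genes rose and 1168 fell in both, against 71.7 and 157.0 for independent lists. Both still use the same estimate of each gene's spread, so their calls are not independent. The changes, which do not use that estimate, correlated at 0.72, with a covariance of 0.226 against 0 in the simulation. Changes with TRAIL alone had a covariance of 0.041 with those of taurolidine and 0.038 with those of the combination, against 0.038 and 0.039 in the simulation. Genes are not independent replicates in these correlations.

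Within each line the largest changes were described as values of 1 array against another, without a test. With taurolidine, RNA45SN5, FOS and ARC rose most in A-204 (5.91, 4.18 and 3.89), FOS, HSPA6 and FOSB in SK-LMS-1 (7.45, 6.64 and 5.14), and RNA45SN5, FOSB and FOS in VA-ES-BJ (6.50, 5.80 and 4.08). The lowest were KCTD21, DUSP16 and ZNF668 in A-204 (-4.69, -4.20 and -4.13), ZNF792, WDCP and ZKSCAN4 in SK-LMS-1 (-4.92, -4.01 and -3.88), and MED26, HIC2 and ZNF680 in VA-ES-BJ (-4.89, -4.52 and -4.38). With both agents the highest were RNA45SN5, NKX6-2 and FOS in A-204 (6.22, 3.91 and 3.88), FOS, HSPA6 and FOSB in SK-LMS-1 (7.50, 6.68 and 5.15), and RNA45SN5, FOSB and FOS in VA-ES-BJ (6.28, 5.86 and 4.37). The lowest were KIF7, WDCP and GPR39 in A-204 (-4.69, -4.67 and -4.49), ZNF792, WDCP and MRPL20-AS1 in SK-LMS-1 (-5.08, -3.90 and -3.78), and SMAD7, MED26 and LOC652276 in VA-ES-BJ (-4.20, -4.15 and -4.12). All of these lowest genes were under the table median on the treated array, so their order depends on the added constant. The same limit holds for ARC and NKX6-2 in A-204, FOS in SK-LMS-1 and FOSB in VA-ES-BJ. Their untreated signals of 18.1, 18.7, 108 and 35.7 were under the table median. Among genes over it on both arrays, the lowest with taurolidine were ZNF804A, CCDC12 and PRAG1 in A-204 (-3.90, -3.53 and -3.38), CCDC12, GEMIN4 and MED26 in SK-LMS-1 (-3.08, -2.93 and -2.92), and CCNF, ZNF107 and CCDC12 in VA-ES-BJ (-3.70, -3.50 and -3.31).

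With TRAIL alone the extremes within a line were under the table median on at least 1 of the 2 arrays compared, and LOC100507351 and EPHX4 on both. They were TFAP4, RPL13AP17 and KRT85 (3.62, 2.88 and 2.83) and TENM4, PKD2L1 and LOC100507351 (-3.18, -3.17 and -3.02) in A-204. In SK-LMS-1 they were HES4, SH2D1A and LOC105372255 (3.41, 3.17 and 3.14) and BCL2L15, PSG3 and CDH23 (-3.22, -3.11 and -3.11). In VA-ES-BJ they were CCNP, ZNF572 and CAPNS2 (3.36, 3.15 and 2.94) and DSCAM-AS1, VSNL1 and EPHX4 (-3.28, -3.23 and -3.14). HES4, for example, had a signal of 436 with TRAIL and 30.5 without.

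At least 2-fold higher and lower with taurolidine were 544 and 1489 genes in A-204, 616 and 1129 in SK-LMS-1, and 439 and 1131 in VA-ES-BJ. With TRAIL these counts were 326 and 362, 413 and 630, and 251 and 550, and with both agents 677 and 1657, 699 and 988, and 400 and 1134. Among genes over the table median on both arrays, a restriction chosen after seeing the data, the counts were 145 and 954, 177 and 563, and 71 and 709 with taurolidine, and 17 and 19, 69 and 39, and 17 and 41 with TRAIL. Changes correlated across genes between lines at 0.38 to 0.47 for taurolidine, 0.02 to 0.05 for TRAIL and 0.37 to 0.44 for both agents.

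The change with taurolidine differed between the lines for 193 genes in a test chosen after seeing the data, which takes arrays with and without TRAIL as repeats of a line (limma, adjusted p under 0.05). ID2, an inhibitor of differentiation factors, was 4.55 higher in SK-LMS-1, 1.31 in A-204 and 0.13 in VA-ES-BJ (adjusted p = 0.00048). TRIB1, a pseudokinase gene, was -2.54 in A-204 and 2.15 in SK-LMS-1 (adjusted p = 0.00073). DDIT4, an inhibitor of mTORC1 signalling induced by stress, went from a signal of 869 to 3040 in SK-LMS-1 and changed by -1.60 in A-204 and -2.65 in VA-ES-BJ (adjusted p = 0.0014). HMGA2, a chromatin protein gene, was -2.03 in A-204, -2.59 in SK-LMS-1 and -0.10 in VA-ES-BJ (adjusted p = 0.0060). In 95 of the 193 genes the differences with taurolidine, without and with TRAIL, were both above 0 in 1 line and both below 0 in another, whatever their size. Of the 193 genes 39 also passed for taurolidine over the lines, and 89 genes passed without the VA-ES-BJ array with TRAIL. The matching test for TRAIL called 0 genes (limma, 486 at an unadjusted p under 0.05, smallest adjusted p 0.158), where 711 are expected with no difference. It leaves the line differences in the change with taurolidine in its error and can be too strict. Its 0 therefore cannot be set against the 193 for taurolidine.

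**Figure D3:**
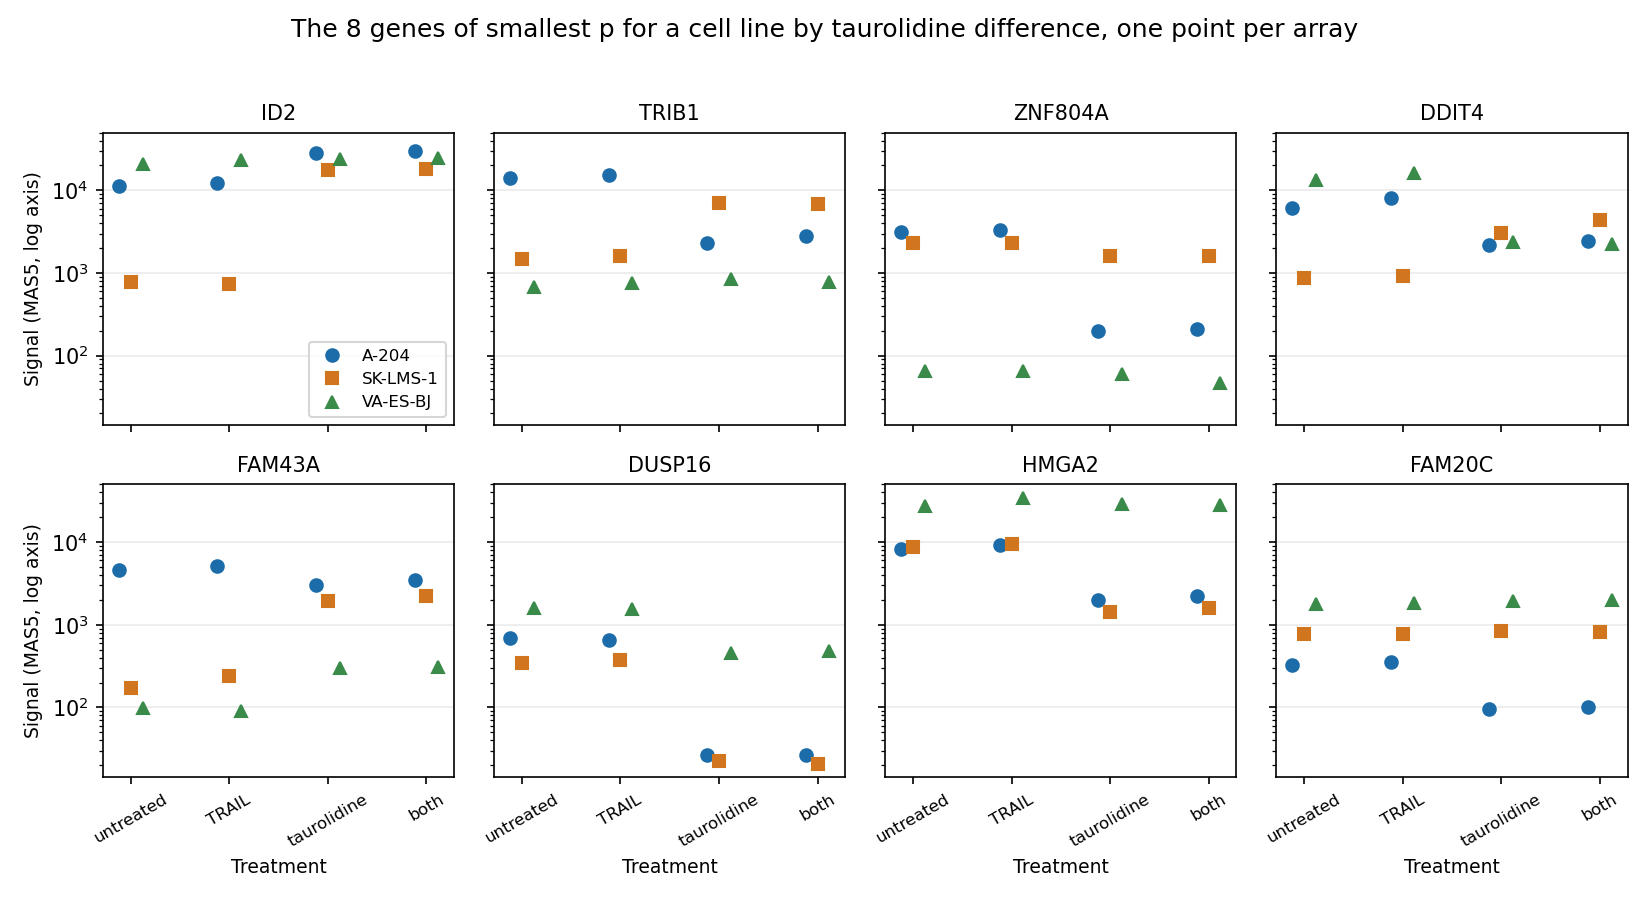
MAS5 signal on a log axis of the 8 genes with the smallest p for a difference between cell lines in the change with taurolidine, by treatment, with 1 point per array. ID2 in SK-LMS-1 stood at 787 and 730 without taurolidine and at 17700 and 18300 with it, while TRIB1 was lower with taurolidine in A-204 and higher in SK-LMS-1.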

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

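The test of differences between lines, the tests on the control probe sets and the tests on the 45S RNA were chosen after the results were seen; the tests on the zinc finger genes were written before those tests were run, on a class of genes picked after the data were seen.

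The change with taurolidine differed between the cell lines for 193 genes. The distance between the highest and the lowest line was 4.42 on the log2 scale for ID2, 4.69 for TRIB1, 3.66 for ZNF804A, 4.65 for DDIT4, 3.86 for FAM43A, 2.44 for DUSP16, 2.49 for HMGA2 and 1.80 for FAM20C, the 8 genes with the smallest p in that test. The ratio of 3' to 5' signal of a further control transcript was 0.82 higher with taurolidine, a signal outside the comparisons of genes, while those of GAPDH and ACTB differed by 0.

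The poly-A spike-in signal was 0.59 higher with taurolidine, also outside the comparisons of genes. Brighter arrays or the authors' scaling would raise the hybridisation controls as much, but the poly-A rise exceeded theirs by 0.62 with a standard error of 0.15. This excess depends in part on the VA-ES-BJ array with TRAIL, whose hybridisation controls were 1.82-fold brighter than those of the line's other arrays. From the untreated to the taurolidine array of that line, the hybridisation controls went from -0.43 to -0.12 and the poly-A spikes from -0.202 to 0.345. These are log2 deviations from the line's mean. Unequal input within the 4 to 5 µg of the labels' protocols allows a rise of 0.32, and the rise less 2 standard errors was 0.46. With only 3 lines, 2 standard errors are a lenient bound, so neither of these explanations is excluded. Less messenger RNA per unit of total RNA after taurolidine may account for it as a hypothesis. Its only test was the rise itself, with the spikes higher in both taurolidine arrays of every line (exact permutation p = 0.0093, the smallest possible). That rise does not tell it from a different amount of spike added to those samples, which was not tested and stays open. With less messenger RNA, many genes counted as higher would not have risen in absolute amount, as spike scaling left 34 genes higher.

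The RNA45SN5 probe set with the highest mean rose more with taurolidine than any other gene named for it, by 5.64, and the other 45S probe set rose by 4.85. Carry-over of ribosomal RNA into the label would raise the 18S and 28S control probe sets by a like amount, and these were 0.47 higher (standard error 0.21) against 5.35 (0.52). A fault of a single probe set is argued against by the other 45S probe set, whose smallest rise in a line was 3.21. A lower share of messenger RNA would raise it no more than the spikes, whose rise plus 2 standard errors was 0.73, against a 45S rise less 2 standard errors of 4.32. Accumulation of 45S precursor or its polyadenylated fragments after taurolidine is a hypothesis that may account for it, found and tested on the same data.

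The counts were set against other splits of the same arrays. For taurolidine, the combination and taurolidine added to TRAIL, 1 of 10 splits gave as many genes, the real one, with 2729, 2679 and 2298 genes against a highest other count of 0; the 10 splits are too few for a share under 0.05. For TRAIL and for TRAIL added to taurolidine the real count was 0, which each of the 10 splits reaches by construction, so nothing follows; the highest other counts were 0 and 1. For the F test, 3 of 100 arrangements of treatments within lines, the real one included, reached the real 2551, with a highest other count of 2619. Only 5 of the random arrangements kept the 2 taurolidine arrays of each line together, and the other random ones called at most 1 gene. The share thus mostly reflects how many such arrangements were drawn, and it does not exclude chance. For the departure from additivity the real count was 0, which all 100 arrangements reach by construction, so nothing follows about chance; the highest other count was 4915. That count came from 1 of 5 arrangements that kept the 2 taurolidine arrays of each line together, which points to taurolidine as the structure of these arrays; among the rest the highest counts were 2 and, for the F test, 1.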

How the results depend on the processing

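Scaling to the spikes, leaving out the VA-ES-BJ array with TRAIL, the main effects and the restriction to bright genes were chosen after seeing the data, the other alternatives before. For taurolidine, the combination, taurolidine added to TRAIL and the F test, the counts were 1650, 1535, 1157 and 1433 without the filter, where more genes are tested, and TRAIL added to taurolidine gave 1. Without the cell line as a block they were 143, 158, 146 and 185 with the pairing left out, since differences between lines then count as error. With only the arrays of the groups compared the first 3 were 0, since fewer arrays enter. Spike scaling gave 8351, 5062, 6482 and 8180, as its construction moves every gene. Leaving out a line gave 354 to 415, 232 to 499, 256 to 479 and 217 to 339, with fewer arrays. Without the VA-ES-BJ array with TRAIL, the counts were 2629, 2605, 1411 and 2023; the cause of the change to 1411 was not tested. The main effect of taurolidine gave 5147 genes, with more arrays in each group. The other alternatives kept these counts within 1.5 times, and TRAIL alone and the departure from additivity were at 0 under every alternative run. The departure and the F test use all 12 arrays and were not run on fewer groups.

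Of 30 lists, camera called 10, 6, 14, 5 and 3 for taurolidine, TRAIL, the combination, taurolidine added to TRAIL and the departure at the preset correlation and 0 with an estimated one. Fry, which sets a list against no other genes, called 0 for TRAIL and for the departure and 11 for taurolidine added to TRAIL. Under spike scaling the medians of lists called with taurolidine turned to -0.37 (NRF2), -0.39 (aminoacyl-tRNA synthetases), -0.28 (metallothioneins), -0.42 (S phase), -0.35 (hypoxia), -0.32 (proteasome), -0.34 (ribosomal), -0.12 (histones) and -0.21 (oxidative phosphorylation). With the combination they turned to -0.19 (NRF2, aminoacyl-tRNA synthetases and smooth muscle), -0.16 (heat shock and hypoxia), -0.28 (endoplasmic reticulum), -0.12 (metallothioneins and ribosomal), -0.27 (S phase), -0.14 (proteasome) and -0.043 (oxidative phosphorylation). The median of aminoacyl-tRNA synthetases with TRAIL was 0.15 without SK-LMS-1 and -5.7e-05 without VA-ES-BJ, and the cause was not tested. Of the 30 medians of lists called for taurolidine, TRAIL or the combination, 16 moved by more than their spread between lines under quantile normalisation, 20 under equal medians, 7 with the mean over probe sets and 1 without SK-LMS-1. The 44 passing changes followed gene by gene were those named for taurolidine and for the combination, HSPA6 and RASD1 for taurolidine added to TRAIL, and CASP8 and XIAP with taurolidine. None of them turned in the alternatives that follow; 18 lost the threshold without the cell line as a block, 16, 14 and 19 without A-204, SK-LMS-1 and VA-ES-BJ, 3 with the mean over probe sets, 1 without the constant and 0 under quantile normalisation or equal medians.

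Within lines, 56 of 90 counts under alternatives stayed within 1.5 times. Without the filter, which adds dim genes, the counts higher and lower were 1439 and 2337 in A-204, 1329 and 2161 in SK-LMS-1 and 1294 and 1858 in VA-ES-BJ with taurolidine. With TRAIL they were 1213 and 1206, 1011 and 1695, and 1014 and 1450. With both agents 1873 were higher in A-204, 1410 and 1962 higher and lower in SK-LMS-1, and 1236 and 1864 in VA-ES-BJ. Among genes over the table median on both arrays, which removes dim genes, they were 145 and 954, 177 and 563, and 71 and 709 with taurolidine, and 17 and 19, 69 and 39, and 17 and 41 with TRAIL. With both agents 162 were higher in A-204, 209 and 500 higher and lower in SK-LMS-1, and 74 and 676 in VA-ES-BJ. A gene near the table median can move by 2-fold or more between arrays without passing any test. The counts thus depend on how many dim genes enter, and signal over background was not measured.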

Other observations

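The class of zinc finger genes and the other classes of gene symbols were picked after the data were seen, and the tests on the zinc finger genes were written before they were run.

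Genes of the zinc finger type passed as lower with taurolidine more often than other genes. Of 414 tested genes with a ZNF, ZFP, ZSCAN or ZKSCAN symbol 182 fell and 4 rose (44.0% lower), against 1448 lower and 1095 higher of 13807 other genes (10.5% lower). The median change of the class was, without a test within a line, -0.77 in A-204, -0.58 in SK-LMS-1 and -0.66 in VA-ES-BJ, and with both agents 183 fell and 4 rose. Of 38 BTB zinc finger genes 23 fell and 1 rose (Fisher's exact test, adjusted p = 1.8e-11 over 32 tests), and of 29 Mediator subunits 8 fell and 2 rose (adjusted p = 0.040 for lower), as 12 of 48 ubiquitin-specific protease genes fell and 1 rose (adjusted p = 0.031 for lower). Of 16 such classes, TAF, KCTD and DUSP genes did not pass as lower (adjusted p = 0.094, 0.13 and 0.19). Antisense, LINC and solute carrier genes passed less often than other genes in both directions, and divergent transcripts did so as lower. Mitochondrial ribosomal protein genes went the other way, with 23 of 76 higher and 3 lower (adjusted p = 7.3e-08), and 6 of 14 RNA polymerase II subunit genes rose (adjusted p = 0.0023). Under spike scaling, where nearly all calls were lower, the direction of genes counted as higher is not fixed. Fisher's exact test takes genes as independent, which genes of the same arrays are not, so these p-values may overstate the evidence.

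The share of zinc finger genes that fell was set against 3 technical explanations. Dim signal is argued against by 1000 draws of other genes matched on mean signal, in which at most 16.9% fell, against 44.0%. The scaling of the arrays is argued against by the median relative to all genes under quantile normalisation, which was -0.55, with 139 lower and 7 higher. Equal medians and spike scaling move all genes of an array alike and test nothing here. Probe sets shared by relatives are argued against by the genes measured with a probe set of the plain design, of which 43.4% fell, against 11.7% of other such genes (Fisher's exact test p = 6.4e-41). That p-value has the same limit, as genes are not independent replicates. A biological response to taurolidine, such as a stop in the making of short-lived messenger RNAs, may account for it as a hypothesis, since RNA half-lives were not measured here. A stop for all genes from the start is argued against by the 26 immediate-early and AP-1 genes, of which 8 rose and 1 fell, with FOS 37.7-fold higher. Their median of 0.70 was 0.07 under spike scaling. Values at 6 h alone cannot tell whether these genes rose before a later stop of all genes, so that stays open.

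Among genes passing for taurolidine, 1508 had another tested probe set; for 367 at least 1 of these had the opposite sign, and for 21 it also passed. Of 4060 tested probe sets without a listed gene, 130 were higher and 259 lower. The lys spike stood 1.91 to 2.02 above the other poly-A spikes in VA-ES-BJ and 0.24 to 0.40 above them in the other lines, on the log2 scale.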
